A study of Caenorhabditis elegans with 2 samples.

How the data were processed

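Late embryos of strain OP201, which stably expresses PQM-1 with a C-terminal GFP-FLAG tag, were used for anti-GFP chromatin immunoprecipitation after sonication, per the labels. The 2 samples are biological replicates of 1 group, per the labels, and were taken 2 h after synchronization. The authors deposited 8 peak lists, 4 in build ce10 and 4 in ce11: 1 for each replicate, 1 for the pooled replicates and 1 reproducible list made from both replicates' lists and the pooled list by irreproducible discovery rate, per the deposited README text and list names. Peaks were thus called by the authors per replicate and on pooled replicates. The aligner, the peak caller, its version and the reproducibility threshold are not given in the sources used here. Control libraries are named in the labels and are not analysed here.

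The deposited signal of each region is the authors' peak signal value, not scaled between lists. The deposited −log10 q-value of each region is the authors' false discovery rate, and the p-value column is unset. Replicate and pooled lists hold relaxed calls: 28996 regions for replicate 1, 23228 for replicate 2 and 27694 for the pooled list in ce11, of which 999, 1305 and 1241 have a q-value of at most 0.01 in the authors' lists. The reproducible list in ce11 equals the 669 strongest pooled regions, and in ce10 the 973 strongest of 27726. Read counts and depth are unknown, so no precision from depth is given; intervals are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

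The supplied annotation, Ensembl release 115 for WBcel235, and the RefSeq genome of that assembly correspond to ce11; 0 regions of the ce11 lists lie beyond a chromosome end. The ce11 lists are the main ones and no coordinates were converted. Summits were taken from the authors' offsets. A promoter ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start, and a gene was bound if a summit lay inside. Small RNA genes were the annotated tRNA, snoRNA, snRNA and rRNA genes extended by 200 bp. Replicates were compared by whether a peak's summit lay inside a replicate's region, that is an overlap of at least 1 bp at the summit, among the 669 strongest regions. Shares by location were compared with 1000 circular shifts of all summits (one-sided). The X share was tested by a two-sided exact binomial test. For 8 patterns, windows reaching 100 bp to each side of the summit were compared with windows 500 bp to each side by a two-sided exact McNemar test against a randomly drawn side. The 20 gene lists were tested by two-sided Fisher's exact tests against all 19973 protein-coding genes on the 6 nuclear chromosomes; 6 listed symbols matched no protein-coding gene. Adjusted p are Benjamini-Hochberg values with a threshold of 0.05. Loci on the transgene were compared with 1000 random genes.

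Named genes followed a rule set before the data were examined: the gene nearest each of the 12 strongest peaks, up to 4 bound members of each list with the strongest peaks, and pqm-1, daf-16, unc-119 and elt-2 in any case. The tests, lists and most alternatives were also set before the data were examined. Alternatives were the stronger 50% of the peaks, the strongest pooled regions, each replicate's own strongest regions, other overlaps, promoter windows, window widths, flanks at 1000 bp, shuffled windows, the other build, nearest genes within 1000 bp only, another background and circular shifts. The alternatives without peaks beside small RNA genes and with pooled regions at a q-value of at most 0.01 were chosen after seeing the data.

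The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data in 20 sets of 669 random positions. TGATAAG planted at 9.87% of summits was called in 20 sets, with 1 call in 160 motif tests when nothing was planted. For gene lists, 550 genes were drawn from 19973; ribosomal genes drawn with a weight of 10 were called in 20 sets, with 0 calls in 400 list tests when genes were drawn evenly. Random positions gave a promoter call in 1 set and a small RNA gene call in 1 set, and X at its expected share was called in 2 sets. Simulated genes were drawn independently, whereas 296 of the 550 bound genes shared their strongest peak with another. Simulated summits with nothing planted lay anywhere in the genome, not mostly in promoters. These rates of false calls thus do not cover shared peaks or the sequence around promoters.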

Results

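The binding of PQM-1, a zinc finger transcription factor tied to insulin signalling and to the DAF-16 associated element TGATAAG, was measured by chromatin immunoprecipitation and sequencing in late embryos of the nematode Caenorhabditis elegans. The strain OP201 carries PQM-1 fused to GFP and FLAG on an integrated transgene in an unc-119 mutant background, and the tagged protein was precipitated with an anti-GFP antibody from whole hermaphrodite embryos 2 h after egg bleaching, per the labels. The series holds 1 group with 2 biological replicates, so no test between groups was possible and the comparisons below set binding sites against the rest of the genome. The peak lists give no read counts, so the depth of each library is unknown. All positions are in build ce11, and signal values are the authors' own, used only to rank or describe regions within a list.

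The authors' reproducible list, which equals the 669 strongest pooled regions, held regions up to 430 bp wide, not all of them strong in both replicates. Its strongest peak, with a signal of 756, lay on chromosome III from 8043770 to 8044151, between genes and 525 bp upstream of K12H4.5, and ranked 1 in each replicate's own list. The next in order of signal lay near M01F1.9 (III, summit 3500049, signal 384.1), near pxn-1 (V, summit 8500548, 357.3) and near nas-30 (I, summit 933518, between genes, 356.2). Those near M01F1.9 and pxn-1 lay in an intron of a protein-coding gene, not necessarily of the gene named. Further strong peaks lay nearest to F55C5.17, W03C9.1, str-56, tasp-1, eel-1, vps-51, Y41D4A.4 and F16G10.6, and of these 12 strongest peaks 7 were in promoters and 4 lay within 200 bp of a snoRNA gene. Only 1 of these 12 held TGATAAG, that of F16G10.6 at rank 12 with a signal of 275.8. Its site at II from 2378742 to 2378748 was 38 bp from the summit.

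The first comparison asked how far the replicates found the same regions. Of the 669 peaks, 526 (78.6%) had their summit in one of the 669 strongest regions of replicate 1 and 546 (81.6%) in those of replicate 2. Both held for 418 peaks (62.5%, exact 95% interval 58.7 to 66.2), including those of mex-1, rpl-15 and rpl-3, and neither held for 15. The signal of the replicates correlated across 668 regions with a Spearman coefficient of 0.441 (two-sided permutation p = 1e-05, the smallest that 100000 permutations give); regions are not independent replicates, and they were selected on the pooled signal. Intervals here and below cover counting error only. The share in both replicates was 56.2% when regions had to overlap reciprocally by 50%.

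**Figure D1:**
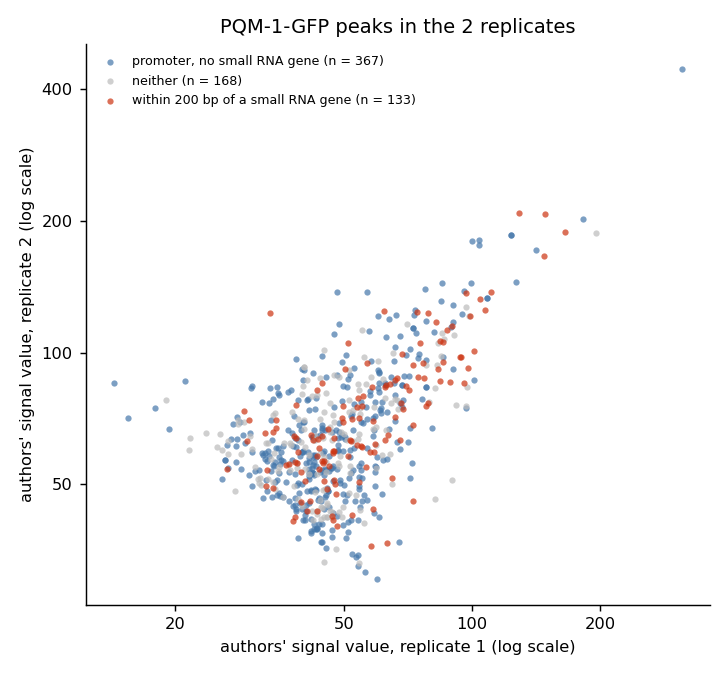
Authors' signal value of each peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale); each point is a peak, coloured by whether its summit is within 200 bp of a small RNA gene, otherwise in a promoter, or neither. Over 668 peaks with a region in both lists the Spearman coefficient was 0.441, and the strongest peak, near K12H4.5, stands apart at 311.4 and 443.6.

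The second comparison asked where in the genome the peaks lay. Promoters of protein-coding genes held 408 of the 669 summits (61.0%, 57.2 to 64.7), against 25.8% ± 1.76 (SD) over 1000 circular shifts of the summits along their chromosomes. Promoter summits lay at a median of 229 bp from a transcript start and 92.9% of them were upstream of it. Examples were tasp-1 (60 bp) and vps-51 (177 bp). The promoter window reaches 1000 bp upstream and 200 bp downstream, so most summits in it would be upstream even if placed evenly. The upstream share was not compared with shifted summits. A further group stood beside genes of small structural RNAs: 133 summits (19.9%, 16.9 to 23.1) were within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene, against 0.545% ± 0.2996 after shifting. tRNA genes, the adaptors of translation, accounted for 80 of these summits, snoRNA genes, which guide RNA modification, for 45, and snRNA genes, which encode parts of the spliceosome, for 9. The 20 rRNA genes had 0 (upper exact limit 0.550%), against a mean of 0.104 summits after shifting, so they are too few to compare. The one-sided permutation p was 0.000999 for promoters and for each of these classes except rRNA, the smallest that 1000 shifts give. By annotation 457 summits lay between genes, 176 in introns, 26 in 5' UTRs, 6 in coding exons and 3 in 3' UTRs. Among the 100 strongest peaks 33 stood beside a small RNA gene and 3 held TGATAAG.

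The X chromosome held 135 of the 669 peaks (20.2%), among them those of hsp-3, ftt-2, cebp-1, lbp-3 and elt-2, against 13.7% of protein-coding genes (exact two-sided binomial p = 3.5e-06). Promoter peaks alone lay on X in 13.97% of cases (exact binomial p = 0.83), and peaks outside promoters in 29.9%. Against X's 17.7% share of chromosome length the same 20.2% did not pass the threshold (exact binomial p = 0.094).

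The third comparison asked which sequence patterns marked the summits. TGATAAG, the DAF-16 associated element, was present in 67 of 669 windows reaching 100 bp to each side of the summit (10.0%), against 3.44% of windows 500 bp to each side (exact adjusted p = 0.00012, exact McNemar test with Benjamini-Hochberg adjustment over 8 patterns). GAGAGAGA was present at 12.1% of summits against 1.57% of flanks (exact adjusted p = 6.2e-13), and the E-box CACGTG at 7.03% against 3.81% (exact adjusted p = 0.0089). The heat shock element TTCNNGAA (8.52% against 14.3%, exact adjusted p = 0.0049) and the T-block TTTTTTT (21.1% against 35.4%, exact adjusted p = 6.1e-09) were rarer at summits than beside them. The general GATA site WGATAR, at 34.98% against 35.5% (exact adjusted p = 0.70), the SKN-1 site WWTRTCAT, at 7.92% against 10.6% (0.21), and the FOXO site GTAAACA, at 2.84% against 2.47% (0.87), did not pass in these exact tests. Each TGATAAG is also a match to WGATAR, and WGATAR away from TGATAAG was not tested here or below. In all 5 of the 8 patterns passed the threshold, 3 more frequent at summits and 2 less frequent. TGATAAG lay a median of 38 bp from the summit and within 50 bp in 50 of its 67 peaks.

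Split by class of peak, a split chosen after seeing the data, TGATAAG was present at 14.8% of the 169 peaks that were neither in a promoter nor beside a small RNA gene, against 1.78% of their flanks, and at 11.2% of the 367 promoter peaks away from such genes, against 4.36%. Of the 133 peaks beside small RNA genes 1 held it (0.752%, exact upper limit 4.12%), against 3.01% of flanks. WGATAR was at 48.5% of summits against 37.3% of flanks in the first class (exact adjusted p = 0.026), at 33.5% against 34.2% at promoter peaks (0.68) and at 21.8% against 36.8% beside small RNA genes (0.039). CACGTG was at 13.02% against 1.18% in the first class (exact adjusted p = 7.2e-05), at 5.72% against 4.22% at promoter peaks (0.68) and at 3.01% against 6.02% beside small RNA genes (0.24). Beside small RNA genes WWTRTCAT passed as rarer at summits (2.26% against 12.8%, exact adjusted p = 0.0068) and GAGAGAGA did not pass (7.52% against 1.504%, exact adjusted p = 0.24). At promoter peaks TTCNNGAA did not pass (11.2% against 15.1%, exact adjusted p = 0.062). Differences between classes were not tested for patterns other than TGATAAG. Over all peaks WGATAR was more frequent at summits than in shuffled copies of the same windows (34.98% against 25.4%, exact adjusted p = 0.00017), and than in flanks in the strongest regions of replicate 2 alone (40.7% against 35.6%, exact adjusted p = 0.0076) and in pooled regions with a q-value of at most 0.01, a setting chosen after seeing the data (40.2% against 35.1%, exact adjusted p = 0.046). WWTRTCAT passed as rarer at summits in windows of 200 bp to each side (15.7% against 20.1%, exact adjusted p = 0.027). CACGTG did not pass in the strongest regions of replicate 2 alone, among the stronger 50% of the peaks, in windows of 50 bp to each side or against shuffled windows (exact adjusted p = 0.28, 0.35, 0.063 and 0.16), and TGATAAG missed the threshold among the stronger 50% (8.68% against 3.74%, exact adjusted p = 0.054). Against shuffled windows TTCNNGAA and TTTTTTT were 1.12 and 1.17 times as frequent at summits and did not pass, and TTCNNGAA also missed the threshold among the stronger 50% and in the narrower windows.

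**Figure D2:**
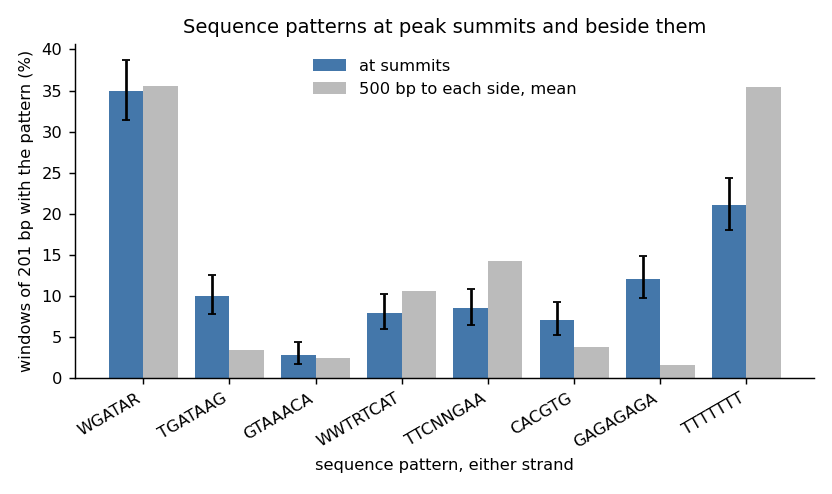
Percent of windows, reaching 100 bp to each side of their centre, holding each sequence pattern on either strand (y axis) at the 669 summits (blue, with exact 95% intervals) and in the windows 500 bp to each side (grey, mean of both sides). TGATAAG, CACGTG and GAGAGAGA were more frequent at summits, TTCNNGAA and TTTTTTT less frequent.

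The fourth comparison asked which genes had a peak in their promoter. These were 550 of 19973 protein-coding genes (2.75%), of which 395 have a symbol, and 144 peaks were shared by 2 or more genes. Of the 20 gene lists fixed before the data were examined, 3 passed the threshold in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists: heat shock proteins and chaperonins, ribosomal proteins and innate immunity. Genes are not independent where they share a promoter peak.

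Heat shock proteins and chaperonins, which fold other proteins, had 7 of 27 members bound (odds ratio 12.5, exact 95% interval 4.45 to 30.9, exact adjusted p = 6.4e-05). Their strongest peaks were those of hsp-3, an endoplasmic reticulum HSP70 (X, summit 6092154, 30 bp from its start, signal 167.3), hsp-90 (V, summit 14685774, signal 157.8), the mitochondrial chaperonin hsp-60 (III, summit 1619113, 144.5) and hsp-1, a cytosolic HSP70 (IV, summit 17278590, 118.9). Of the 81 ribosomal protein genes, 17 were bound (odds ratio 9.64, 5.26 to 16.8, exact adjusted p = 1.2e-09), led by rpl-15 (IV, summit 654927, 236.4), rpl-3 (III, summit 3867563, 229.9), rps-24 (IV, summit 385358, 219.5) and rpl-35 (III, summit 7854687, 170.7). None of the strongest peaks of the bound members of these lists held TGATAAG. Of the bound ribosomal genes 14 of 17, and of the chaperone genes 5 of 7, shared this peak with another bound gene. Counting only the gene with the nearest transcript start, 9 of 81 ribosomal genes (odds ratio 5.63, exact adjusted p = 0.0015) and 4 of 27 chaperone genes (7.76, exact adjusted p = 0.018) were bound. Among the stronger 50% of the peaks these were 6 of 81 (6.06, exact adjusted p = 0.0073) and 6 of 27 (21.7, exact adjusted p = 2.4e-05). Whether promoters of ribosomal and chaperone genes give signal with any antibody was not tested, since no precipitation without the tag was analysed.

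Innate immunity had 5 of 30 members bound (odds ratio 7.12, 2.12 to 19.02, exact adjusted p = 0.0084): the bZIP factor genes cebp-1 (125.2), zip-2 (100.6) and cebp-2 (88.62), the lectin gene clec-86 (90.45) and hlh-30, a TFEB relative (84.54), which was named after its values were seen. This list lost its call in the strongest regions of replicate 1 alone (odds ratio 2.75, exact adjusted p = 0.705), among the stronger 50% of the peaks (2.57, exact adjusted p = 1) and with the narrower promoter of 500 bp upstream and 100 bp downstream (5.44, exact adjusted p = 0.11).

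Genes of the gut were bound in small numbers that did not pass in the main test. Gut proteases and lysozymes had 3 of 28 members bound (odds ratio 4.255, exact adjusted p = 0.20), namely the cathepsin B gene cpr-4 (V, summit 6614555, signal 117.2) and the aspartyl protease genes asp-6 and asp-12, which share a peak between them (V, summit 8269127, 82.47). Circular shifts called this list (adjusted permutation p = 0.00999), but they compare it with shifted positions and not with other genes, and promoters as a whole held 2.36 times their shifted share. Against other genes it passed in the strongest regions of replicate 2 alone (4 of 28, odds ratio 6.10, exact adjusted p = 0.031). In those of replicate 1 alone it did not pass (1 of 28, odds ratio 1.42, exact adjusted p = 1). Of the endoderm regulators 1 of 10 was bound (odds ratio 3.93, exact adjusted p = 0.70): elt-2, the GATA factor that maintains intestinal identity, with a peak on X from 10480432 to 10480861, between genes and 593 bp upstream of its start, at rank 652. Intestinal structure and transport had 2 of 25 bound (odds ratio 3.08, exact adjusted p = 0.50), hmit-1.1 (82.64) and the cell polarity gene let-413 (82.35). This list passed with the promoter widened to 2000 bp upstream and 500 bp downstream (5 of 25, odds ratio 6.59, exact adjusted p = 0.0095) and in pooled regions with a q-value of at most 0.01 (5 of 25, 5.13, exact adjusted p = 0.027). Of these gut peaks that of cpr-4 was among the 669 strongest regions of both replicates, those of elt-2 and hmit-1.1 of replicate 1 alone, and those of asp-6 with asp-12 and of let-413 of replicate 2 alone. The gut peaks named here held TGATAAG: at cpr-4 the site and its surroundings read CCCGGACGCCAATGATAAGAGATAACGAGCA (V from 6614589 to 6614619, plus strand) and at elt-2 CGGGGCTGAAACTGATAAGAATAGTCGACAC (X from 10480704 to 10480734).

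The remaining lists did not pass in the main test either. Insulin and FOXO signalling had 2 of 25 bound, the 14-3-3 genes ftt-2 (193.8) and par-5 (89.74), at an exact adjusted p of 0.50, and passed with the wider promoter (5 of 25, odds ratio 6.59, exact adjusted p = 0.0095). Lipid metabolism had 2 of 43, the fatty acid binding gene lbp-3 (99.08) and the acyl-CoA synthetase gene acs-2 (86.82), at 0.83. Histones had 3 of 72, his-37 (135.8) and the neighbours his-67 and his-68 (100.2), at 0.90. Class II genes lowered by FOXO had asp-12 (1 of 18, exact adjusted p = 0.88), body wall muscle had the cofilin gene unc-60 (1 of 28, 89.68, exact adjusted p = 0.97) and germline and maternal genes had mex-1 (1 of 40, 272.7, exact adjusted p = 1). The mex-1 peak lay 920 bp from its start and also in the promoters of W03C9.5 and rab-7. No member was bound among 8 lists: yolk proteins (6 genes), metal homeostasis (18), class I genes raised by FOXO (27), hypoxia and sulfide response (15), detoxification and oxidative stress (25), epidermis and cuticle (38), pharynx (25) and neurons (40), with adjusted p of 0.97 or 1.

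**Figure D3:**
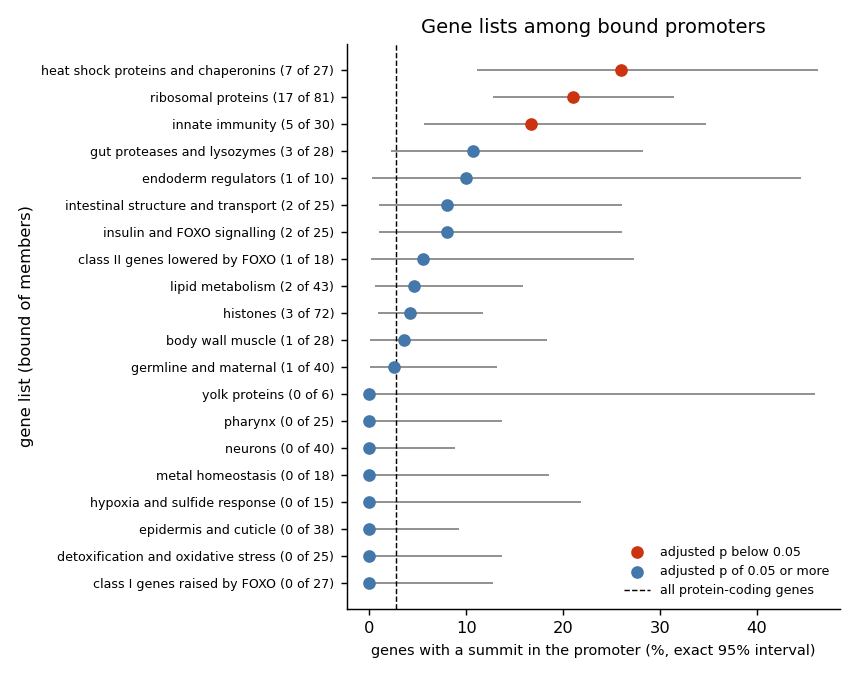
Percent of each gene list with a peak summit in the promoter (x axis, points with exact 95% intervals; bound and total members in brackets), red where the adjusted p was below 0.05. The dashed line marks the 2.75% of all protein-coding genes; heat shock proteins and chaperonins, ribosomal proteins and innate immunity lie above it.

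The last comparison looked at the loci carried on the transgene. No region of the pooled list or of either replicate's own list had its summit within 20 kb of pqm-1 (II from 11150391 to 11152595), which was so for 9, 6 and 7 of 1000 random protein-coding genes in the pooled, replicate 1 and replicate 2 lists. The stretch without a summit was 49427 bp in the pooled list and in replicate 1 and 46655 bp in replicate 2, and held 10 genes from lsm-1 to ptr-13; 27, 12 and 31 stretches as long occurred in the genome. Within 5 kb the absence was shared by 9.6% of random genes. Around unc-119, within 20 kb, the pooled list had 16 regions, the strongest at rank 883, and 74.7% of random genes had as few or fewer per kb. The promoter of daf-16, the FOXO factor gene, had no peak in the reproducible list, and its strongest pooled region was at rank 3372 (I, summit 10762983, signal 45.92, q = 0.136).

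**Figure D4:**
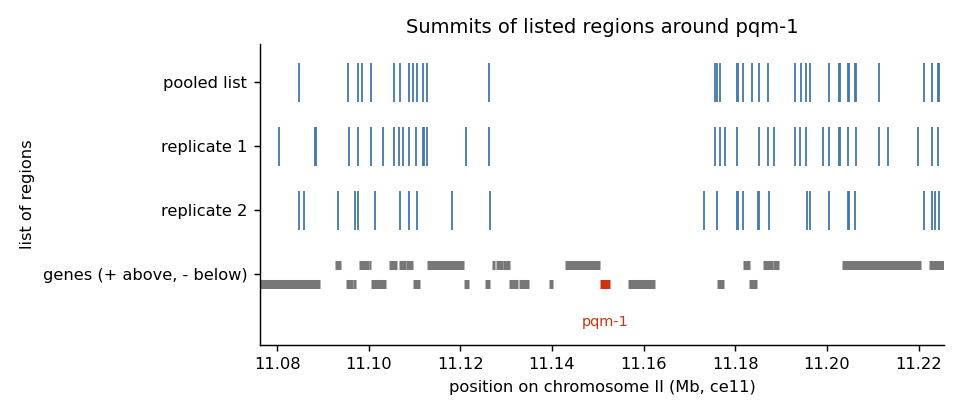
Summits of the regions in the pooled list and each replicate's list (vertical lines) along chromosome II in Mb, with protein-coding genes on the plus strand above and the minus strand below; pqm-1 is in red. None of these lists has a summit in the 46655 bp around pqm-1 that both replicates leave empty.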

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

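The tests of TGATAAG below the reproducible list and beside small RNA genes, of the stretch shared by both replicates and of X without small RNA genes or outside promoters were chosen after the results were seen. Pooled regions at ranks 670 to 2000, outside the reproducible list, held TGATAAG in 13.7% of 1331 summit windows (exact 95% interval 11.9 to 15.7) against 3.98% of flanks (exact McNemar p = 5.3e-18); part of these regions was already used above, in the setting with a q-value of at most 0.01.

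Summits stood beside tRNA, snoRNA and snRNA genes 36.5 times as frequently as after shifting. TGATAAG was held by at most 4.12% of these peaks (exact upper limit), against 12.31% of the 536 others, so most of the others lacked it too. Beside small RNA genes WGATAR (21.8% against 36.8%), WWTRTCAT (2.26% against 12.8%) and TTTTTTT (17.3% against 31.2%) were also rarer at summits than in flanks. The rarity of TGATAAG there thus cannot be told apart from local sequence content, and it does not decide how these peaks are bound. Reads shared between identical gene copies cannot be the whole source. Beside genes whose sequence occurs once in the annotation lay 64 peaks, against a mean of 2.03 after shifting (permutation p = 0.000999, the smallest that 1000 shifts give). Single genes with a peak were mostly snoRNA genes (46 of 346, with 0 snoRNA genes in identical copies), besides 13 of 143 tRNA and 6 of 85 snRNA genes. Copies that were not fully identical counted as single. Of tRNA genes 15.8% of 469 with identical copies and 9.09% of 143 single ones had a peak. Of snRNA genes these were 4.545% of 44 and 7.06% of 85, and neither difference was tested. Shared reads as a partial source stay open, above all for tRNA genes. Also open is signal from highly transcribed genes with any antibody, which a precipitation without the tag could test and which was not analysed here. No biological explanation was tested.

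No listed region lay around pqm-1 over 46655 bp in both replicates. The stretch in the pooled list, 49427 bp long, held 10 genes. At least as many were in 4350 of 10000 windows of its length, so genes were not scarce in it. Of these 4350 windows 0.644% had no pooled region. Stretches that long without a region are rare anywhere (27 of 27688), so this share does not test a lack of promoters. Repeated sequence was not decided by the rule set beforehand: 32.9% of the stretch is soft-masked, against a median of 32.3% and a 95th percentile of 57.03% over 10000 windows. Of these windows 52.26% were masked as little or less, and the genome as a whole at 35.71%. The masked share of the stretch was thus ordinary. Extra copies from the transgene may change the local background in sample or control, and the authors may have filtered this stretch out, but without read depth or a list of their filters these cannot be told apart from other local causes. No biological explanation was tested.

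X held more peaks than its share of promoters. Small RNA genes are not the whole source of this excess over promoters, since 17.7% of the peaks away from them lay on X (exact binomial p = 0.0082 against 13.7%), though against X's 17.7% of length these peaks showed no excess (exact binomial p = 0.95). Outside promoters 29.9% of peaks lay on X (exact binomial p = 1.3e-06 against 17.7% of length), but these include peaks beside small RNA genes, and 45.1% of 612 tRNA genes lie on X. Of the 169 peaks away from both 28.4% lay on X (exact binomial p = 0.00055). Against that yardstick neither promoters nor both sources combined are the whole source. The 17.7% counts promoter sequence too, and X has 13.7% of protein-coding genes, so it is a low expectation for peaks outside promoters. X's share of sequence outside promoters was not computed, so these p may be too small. A biological cause was not tested.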

How the results depend on the processing

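The alternatives without peaks beside small RNA genes and with a q-value of at most 0.01 were chosen after seeing the data. The promoter and small RNA gene shares kept direction and threshold under each alternative run. The strongest pooled regions are the same list by construction and the transgene loci held 0 peaks, so these settings moved nothing. Fewer or more regions, or a wider or narrower window, changed counts by construction; for the rest the cause was not tested, and unknown depth limits what weak regions show. The other build listed 973 peaks. The X share of 20.2% did not pass against length. The summit-to-flank ratio of WGATAR, 0.985 in the report's setting, turned to 1.07 in windows of 50 bp to each side, 1.38 against shuffled windows, 1.09 without small RNA peaks and 1.14 at the q-value limit, and ranged from 0.959 to 1.14 without either replicate. Against shuffled windows the ratio turned to 0.95 for GTAAACA, 1.29 for WWTRTCAT, 1.12 for TTCNNGAA and 1.17 for TTTTTTT. Patterns past the threshold were 2 in the stronger 50% of peaks, 3 in the narrower windows, 3 against shuffled windows, 6 in windows of 200 bp to each side and 6 at the q-value limit. Bound genes were 265 in the stronger 50% and 932 at the q-value limit, and 5 lists passed with the wider promoter, adding intestinal structure and insulin signalling. The 27 bound promoters named by the rule from the lists fell to 21 with the narrower promoter, 22 counting nearest starts only and 13 in the stronger 50%. In the strongest regions of replicate 1 and of replicate 2 alone they fell to 21 and 23. Lost with the narrower promoter were among others hsp-60 and mex-1, with summits 629 and 920 bp from their starts. Agreement was 56.2% with 50% reciprocal overlap and 55.6% for the longer lists of 2N regions. The share of random genes with as few regions as pqm-1 was 9.6% at 5 kb and 32.8% at 50 kb. The odds ratios that turned, all of lists with at most 2 bound members and none past the threshold, were in the stronger 50% 0 for endoderm regulators, intestinal structure, class II genes, lipid metabolism and body wall muscle and 1.91 for germline genes. With the narrower promoter endoderm regulators had 0. With the wider promoter they were 1.54 for metal homeostasis, 1.87 for hypoxia and 0.971 for body wall muscle, and at the q-value limit 2.56, 3.15 and 0.756 for these lists. Body wall muscle had 0.985 against genes with a symbol, and germline genes a ratio of 2.5 to circular shifts, which is no odds ratio against other genes and lies near the 2.36 of promoters as a whole. Without either replicate the ranges were 0 to 4.27 for endoderm regulators, 0 to 2.14 for metal homeostasis, 0 to 2.14 for class II genes and 0 to 1.42 for body wall muscle. No paired analysis was possible because there is 1 group.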

Other observations

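The tests of patterns and gene lists in weaker regions were chosen after results were seen; those of gut genes and of CTGCGTC in weaker regions were set before. Below the reproducible list, at pooled ranks 670 to 2000, the general GATA site WGATAR, which includes each TGATAAG and was not tested without it, was present at 44.4% of summits against 37.0% of flanks (exact McNemar test, adjusted p = 0.0018), GAGAGAGA at 11.8% against 1.65% (1.6e-25) and CACGTG at 6.54% against 3.79% (0.0019). Genes of intestinal structure and transport had 5 of 25 promoters bound by these regions (odds ratio 5.555, adjusted p = 0.039, Fisher's exact test), and ribosomal protein genes 12 of 81 (odds ratio 3.89, adjusted p = 0.0036). Heat shock proteins and chaperonins (3 of 27, exact adjusted p = 0.31) and innate immunity (4 of 30, exact adjusted p = 0.16) did not pass there.

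One hypothesis is that gut genes and genes of ribosomal proteins and chaperones are reached differently. In the reproducible list, 5 of 5 peaks in promoters of the endoderm, intestinal and gut protease lists held TGATAAG and 0 of 24 in promoters of the ribosomal and chaperone lists, but the lists were grouped after this was seen, so no p is given for it. At pooled ranks 670 to 2000 these were 4 of 8 and 0 of 15 (exact Fisher p = 0.0079). Over all regions at these ranks 13.75% held TGATAAG, and 11.17% of promoter peaks away from small RNA genes in the reproducible list did. At these shares most ribosomal and chaperone peaks would lack it too. Promoters of gut genes without a peak were not searched, so a difference in promoter sequence cannot be told apart from a different route. If the hypothesis holds, PQM-1 may be at its element at gut genes and at the others by another route, though the numbers are small. Most of the gut peaks in the reproducible list were among the strongest regions of 1 replicate alone, and no library without the tag was compared.

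A further hypothesis concerns CTGCGTC, a 7-mer picked because it was frequent at the summits (14.2% of 669 windows against 1.20% of flanks). It may mark weaker regions too: at ranks 670 to 2000 it was at 12.1% of summits against 1.62% of flanks (exact McNemar p = 8.1e-25). Within the reproducible list it was most frequent at peaks neither in a promoter nor beside a small RNA gene, at 23.7%, and present at 6.02% of those beside small RNA genes.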
